A study of Homo sapiens with 8 samples.

How the data were processed

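RNA was sequenced from 8 libraries of EPC2-hTERT cells at the air-liquid interface, 4 with a control hairpin (shCtrl) and 4 with a hairpin against HIF1A (HIF1A-KD), as the sample titles assign them. Total RNA was column-purified and libraries were made with a kit that per the labels' protocols was NEBNext Ultra. Per the submitters' processing notes, the tools were bcl2fastq, FastQC 0.11.5, TopHat2 2.0.13, Bowtie2 2.2.3.0, SAMtools 1.3.1, Picard 1.129 and HTSeq 0.6.1. The notes name both GRCh37/hg19 and GRCh38/hg38 without a role. Gene coordinates in the deposited table carry haplotype contig names of hg19, so that build is given here, and the GRCh38 annotation at hand was not used. Whether counting used strand is not given in the sources used here.

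The deposited expression table is named for raw counts but holds RPKM (reads scaled by gene length and library total) made by the authors, for 25369 genes. Multiplying a value by the table's gene length gave whole multiples of a single step per library for 100% of genes with a readable length, within 0.01 read. The steps imply 48422873, 43205845, 52401547 and 47774551 reads for shCtrl 1 to 4, and 45624164, 65326907, 47203836 and 38068729 for HIF1A-KD 1 to 4. These totals set the counting precision, and intervals for single libraries were not computed. For 597 genes the length cell was unreadable, and 28 gene names had turned into dates. The file holds no mitochondrially encoded genes. The authors' second deposited table is a comparison of 13627 genes with a signal per group (mean normalised reads), a moderated fold ratio, its log2 and p-values. The tool behind it is not given in the sources used here. Moderated ratios are drawn towards no change and are not a like measure to the fold changes computed here. Means of the recovered reads after median-of-ratios scaling were within 1% of that table's means for 100% of 13468 genes.

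The design fixed before the data were examined was a quasi-likelihood count test. The deposited values are RPKM and not counts, so the main test was instead limma 3.58.1 (R 4.3.3) on log2(RPKM + 0.1), with trend and robust variance moderation, two-sided, without a block. Of tests on the recovered reads only limma-voom was run, as an alternative, and the quasi-likelihood test was not run on them. Genes with at least 0.5 RPKM in at least 4 libraries were kept, which left 11899. Adjustment was by Benjamini and Hochberg, with a threshold of 0.05. Fold changes are on the log2(RPKM + 0.1) scale, which understates those of low genes. A total of 28 gene lists were fixed before the data were examined, and 24 with at least 3 tested members were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Lists of leukocyte, endothelial and melanocyte markers had too few tested members, and the mitochondrially encoded list had none.

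Libraries of the same number deviated together from their group means, with correlations across genes of 0.754, 0.730, 0.252 and 0.257 for numbers 1 to 4. All were over 0.1, so by a limit set beforehand the number was taken as pairing the libraries, from the data and not from the labels. The limit does not tell partners from other libraries, since shCtrl 1 with HIF1A-KD 2 (0.12) also passed it. Numbers 3 and 4 passed it although the difference of library 3 from 4 correlated across genes at −0.292 between the groups. That value goes against pairing them as numbered. For numbers 3 and 4 this pairing is uncertain, since shCtrl 3 correlated more with HIF1A-KD 4 (0.463) and shCtrl 4 with HIF1A-KD 3 (0.613) than with its own number, and the mean correlation was 0.64 with HIF1A-KD 3 and 4 crossed against 0.498 as numbered. The fit with the number as a block is called the paired fit and is given where it changes a call. Where neither fit is named, an adjusted p of a single gene is from the unpaired test. Libraries 1 and 2 also parted from 3 and 4, an unlabelled split.

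Genes named in the text were chosen by a rule fixed before the data were examined. It took the HIF pathway list, up to 3 called members of each list and up to 2 that went the other way, the 2 most abundant members of lists with no call, the 10 largest rises and falls and the 5 smallest p on each side, and 15 fixed genes. Ranked genes needed at least 5 CPM in a group, computed from RPKM and length, and non-overlapping groups. Genes without a readable length, and those with names such as LOC, LINC or MIR, were left out of the ranking. After the data were seen, the same rule was applied to the paired fit, with 4 pairs moving the same way in place of non-overlapping groups. Some genes that the rule took are not reported here.

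The fits were tested on simulated counts for 11802 genes, with the real means and depths and 200 genes changed. To set pair effects, both libraries of a number were given the same base level, so the pairing as numbered was assumed and not tested. With these pair effects, the unpaired fit recovered 7% of 2-fold and 51% of 4-fold changes, and the paired fit 53% and 76%, with 1 and 11 unchanged genes called. Without pair effects, the unpaired fit recovered 56% and 88% and the paired fit 29% and 76%. There all libraries had the same base level and only the spread within pairs was kept, so these shares do not apply to libraries as variable as the real ones.

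Alternatives were median-of-ratios scaling, no filter, a filter of 1 RPKM, limma-voom on the recovered reads with trimmed-mean scaling, the replicate block, and leaving out each library. Added after seeing the data were pseudocounts of 1 and 0.01, the split of libraries 1 and 2 from 3 and 4, other pairings, and the same alternatives for the paired fit. In the paired fit, leaving out a library also takes its partner out of the estimated group difference, so such fits rest on the remaining pairs. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.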

Results

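Gene expression was measured by RNA sequencing in EPC2-hTERT, a human esophageal epithelial cell line immortalised with telomerase. A stable line with a control short hairpin RNA (shCtrl) was compared with a stable line with a hairpin RNA against HIF1A (HIF1A-KD), with 4 libraries of each, numbered 1 to 4 in the labels. HIF1A encodes the oxygen-regulated subunit of the transcription factor HIF-1. Cells reached confluence over 2 days on membranes with 0.4 µm pores, spent 5 days in medium with 1.8 mM calcium chloride and were then exposed to air for 4 days, a culture in which keratinocytes stratify. The labels also name a vehicle and the hydroxylase inhibitor dimethyloxalylglycine, and assign neither to a library. The read totals implied by the deposited values ran from 38068729 in HIF1A-KD 4 to 65326907 in HIF1A-KD 2. The question, from the series' title, was how HIF-1α relates to metabolism and epithelial differentiation in eosinophilic esophagitis.

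The HIF1A transcript was lower in the HIF1A-KD library of every number. HIF1A (chromosome 14, 62162119 to 62214977, plus strand, hg19) averaged 89.7 ± 29.2 RPKM (SD, n = 4) in shCtrl and 36.6 ± 16.3 RPKM (SD, n = 4) in HIF1A-KD, which was 40.8% of the shCtrl mean. The shCtrl libraries 1 to 4 held 95.2, 51.4, 89.8 and 122 RPKM, and the HIF1A-KD libraries 27.6, 19, 54.8 and 45.0 RPKM. HIF1A-KD 3 therefore lay above shCtrl 2. The log2 change was −1.34 (SE 0.37). It did not pass the unpaired test (adjusted p = 0.319, limma) and passed with the number as a block (adjusted p = 0.0253, SE 0.17). A two-sided exact permutation test of log2 RPKM, 4 against 4 and without the pairing, gave p = 0.0571, where the smallest p possible is 0.0286. The paired call was lost without shCtrl 1 or 2 or HIF1A-KD 1, 2 or 4, and over the settings of the fit paired as numbered its adjusted p ran from 0.00867 to 0.188, against 0.0521 to 0.836 unpaired, and was 0.003426 with HIF1A-KD 3 and 4 crossed. The crossed pairing was chosen after the correlations in these same data were seen, so its value is no independent support. Among libraries numbered 1 and 2 the log2 change of HIF1A was −1.61, and among those numbered 3 and 4 it was −1.08. Of the other 8 tested genes of the HIF pathway list, none passed either test, and adjusted over the list alone HIF1A was the only member called in each fit (camera adjusted p = 0.564). EPAS1, which encodes HIF-2α, held 46.3 ± 13.6 and 48.6 ± 13.7 RPKM (SD, n = 4 each), and the log2 change of ARNT, the partner of HIF-1α, was 0.34 (adjusted p = 0.780; higher in 4 of 4 pairs).

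**Figure D1:**
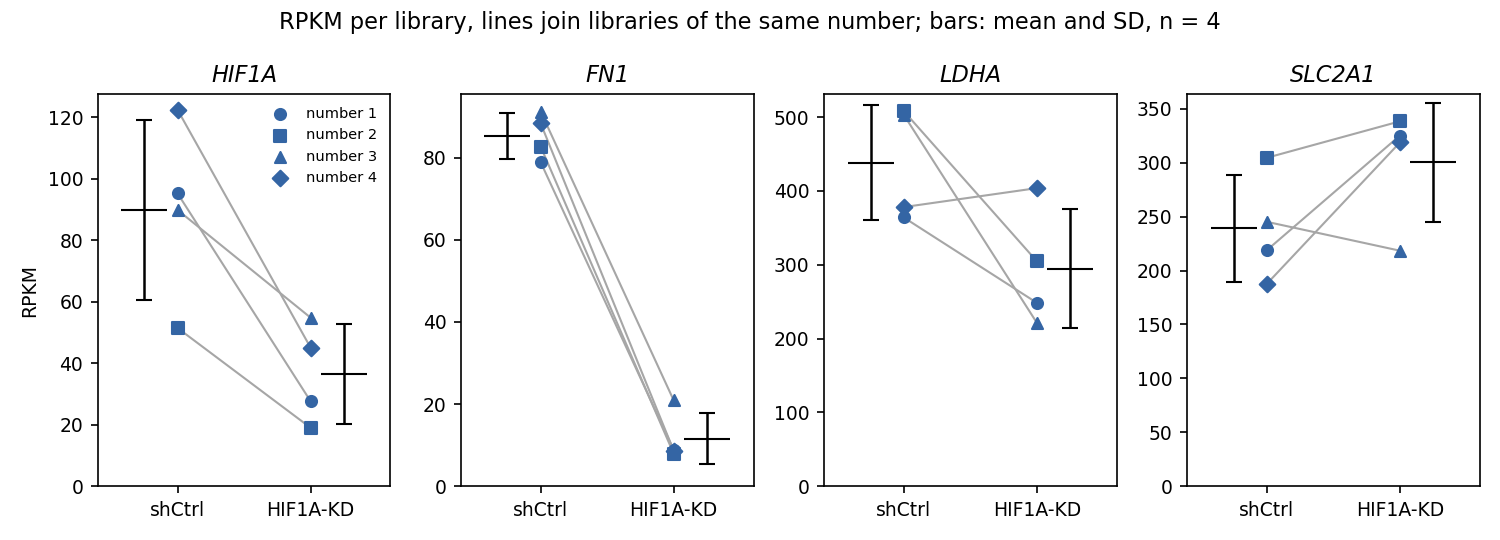
RPKM of HIF1A, FN1, LDHA and SLC2A1 in each library (vertical axes, from 0), for shCtrl and HIF1A-KD, with lines between libraries of the same number and bars for the mean and SD of 4 libraries. HIF1A and FN1 were lower in HIF1A-KD in all 4 pairs, while 1 pair of LDHA and 1 pair of SLC2A1 went against the others.

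The transcripts that passed the unpaired test were lower for fibronectin and a proline-rich protein and higher for 3 other genes. FN1, which encodes fibronectin, fell from 85.3 ± 5.55 to 11.6 ± 6.23 RPKM (SD, n = 4 each; log2 change −3.00, SE 0.29, adjusted p = 0.0157). PRB2, a salivary proline-rich protein gene, fell from 78.1 ± 27.6 to 9.85 ± 2.74 RPKM (log2 change −2.94, adjusted p = 0.0159). TCN1, which encodes a vitamin B12 carrier, rose from 21.5 ± 1.93 to 63.6 ± 4.42 RPKM (log2 change 1.56, adjusted p = 0.0157). The cytochrome P450 gene CYP2C18 rose from 1.94 ± 0.63 to 15.9 ± 6.29 RPKM (log2 change 2.92, adjusted p = 0.0482), and the histone gene HIST1H2BK rose from 23.0 ± 2.95 to 57.2 ± 7.66 RPKM (log2 change 1.31, adjusted p = 0.0482). In hg19 coordinates these genes lie at chromosome 2, 216225179 to 216300791 (FN1), chromosome 12, 11544474 to 11548498 (PRB2), chromosome 11, 59620281 to 59634041 (TCN1), chromosome 10, 96443251 to 96495947 (CYP2C18) and chromosome 6, 27106072 to 27114637 (HIST1H2BK). PRB2, CYP2C18 and HIST1H2BK belong to families of similar genes, so reads may have been split among copies by the authors' counting.

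These 5 genes, 3 higher and 2 lower, were all that passed the unpaired limma test among 11899 genes, and 928 genes reached an unadjusted p of 0.05. Median-of-ratios scaling gave 3 higher and 5 lower. With the library number as a block the count was 218, of which 88 were higher and 130 lower and 132 changed at least 2-fold, and all 5 genes were among them. With HIF1A-KD 3 and 4 crossed, which gave the higher mean correlation between paired libraries, the block called 1327, 212 of the 218 among them. The crossed pairing was chosen after the correlations in these same data were seen, and it keeps pairs 1 and 2 as numbered. Neither its count nor this overlap is therefore independent support for the 218. The paired count fell to 1 without HIF1A-KD 2, to 5 without shCtrl 2, to 20 without shCtrl 1 and to 33 without HIF1A-KD 1. These paired fits rest on the remaining pairs, so they show the weight of a pair and not of a single library. The unpaired count was 3 without shCtrl 1, 1 without shCtrl 2 or without HIF1A-KD 1, 2 without HIF1A-KD 3, and 0 without shCtrl 3, shCtrl 4, HIF1A-KD 2 or HIF1A-KD 4. Limma-voom on the recovered reads called 5, of which 3 were among these. Libraries 1 and 2 stood apart from 3 and 4 along the first principal component (41.9% of the variance). A fit with that split as a term called 102 genes, while libraries 1 and 2 alone called 0 and libraries 3 and 4 alone called 5. The authors' deposited table, which was made from the same libraries and is no independent support, lists 1229 genes at an adjusted p of 0.05, 537 higher and 692 lower. Among them are genes that passed neither fit here, such as LDHA, SPRR3, COL1A1, KRT17, SCD and TGFA. A gene not called here is therefore not shown to be unchanged. Groups did not overlap for 643 genes, 5.40% of those tested. Chance gives 2.86% if all libraries are exchangeable, a value that leaves out the pairing and the split of libraries 1 and 2 from 3 and 4.

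Genes were ranked that passed the paired fit, had at least 5 CPM (reads scaled by the library total) and moved the same way in all 4 pairs. Among these, members of the cornified envelope list had the largest falls. PRR9 (log2 change −3.80), LCE2A (−3.68) and LCE2C (−3.41) are genes of the cornified envelope cluster on chromosome 1. They were followed by PSG7 (−3.19), a gene of a family of similar pregnancy-specific glycoproteins, and then by FN1 and PRB2. WFDC12 (−2.67), AZGP1 (−2.66), SERPINA12 (−2.58) and MME (−2.53), which encodes the surface peptidase neprilysin, also fell. CDSN (−2.72) passed the paired fit too, but its length was unreadable and it was not ranked. The largest rises were in CRISP3 (4.65), DAPL1 (4.22), SERPINB11 (3.19), FAM3D (3.08) and the protease gene TMPRSS11A (3.02), then in CYP2C18, CXCL17 (2.73), MERTK (2.59), the noncoding RNA H19 (2.30) and the early suprabasal keratin KRT10 (2.30). LOC645638, with a moderated log2 change of 2.43 in the authors' deposited table, was not ranked, since LOC names were left out. H19 and CRISP3 had 2.01 and 2.92 in that table, so its values are not comparable with those here. CRISP3 went from 1.07 ± 1.05 to 23.3 ± 13.2 RPKM (SD, n = 4 each; paired adjusted p = 0.00934; shCtrl mean 0.643 RPKM without shCtrl 4), and H19 from 254 ± 117 to 1161 ± 263 RPKM (paired adjusted p = 0.00488). That the ranked genes moved the same way in all 4 pairs was a condition of the ranking and not a result. The shCtrl means of PRR9, LCE2A, LCE2C, PSG7, WFDC12, AZGP1 and SERPINA12 rest largely on shCtrl 1. In the paired fit without it, which rests on the remaining pairs, LCE2A (−3.13, paired adjusted p = 0.0601), LCE2C (−2.89, 0.124), PSG7 (−2.68, 0.204) and SERPINA12 (−2.27, 0.221) did not pass. Apart from FN1, PRB2 and CYP2C18 the ranked genes named here did not pass the unpaired test, where the adjusted p ranged from 0.0629 for H19, AZGP1 and MME to 0.754 for SERPINA12. Of the 44 named genes that passed the paired fit, 0 passed without HIF1A-KD 2, 4 without shCtrl 2, 16 without shCtrl 1 and 21 without HIF1A-KD 1. They moved the same way in all 4 pairs, so leaving out a pair could not change their direction.

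**Figure D2:**
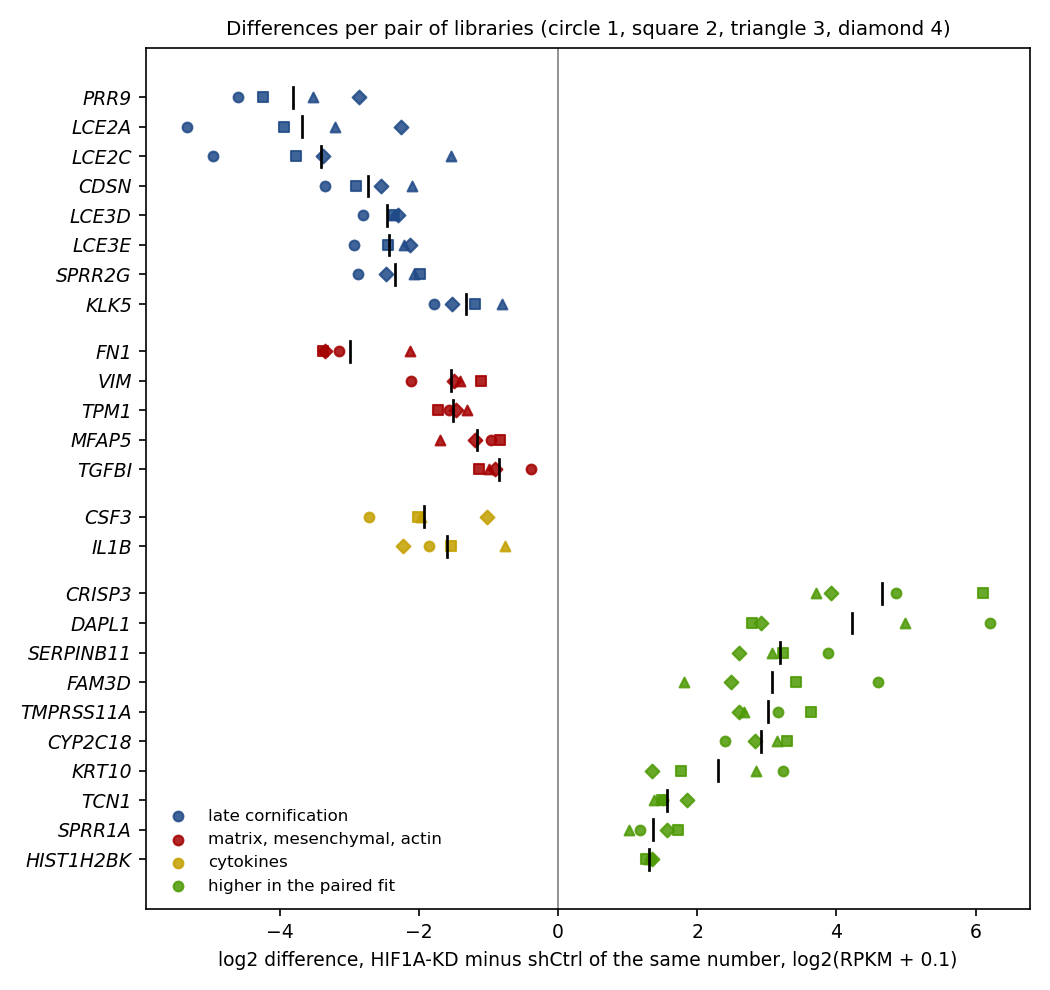
Difference in log2(RPKM + 0.1) between HIF1A-KD and shCtrl libraries of the same number (horizontal axis) for 25 genes that passed the paired fit, with a symbol per pair and a bar at the mean of 4 pairs. All 4 pairs of each gene lie on the same side of 0, from PRR9 at −3.80 to CRISP3 at 4.65. For genes taken by rank this was a condition of the choice.

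Cornified envelope precursors were lower as a list by camera with a preset correlation of 0.01 (adjusted p = 2.49e-06), and not with an estimated correlation (adjusted p = 0.213). In the paired fit 7 of the 36 tested members fell, including LCE3D (2796 ± 3308 to 447 ± 449 RPKM, SD, n = 4 each; paired adjusted p = 0.00147), LCE3E (1155 ± 1228 to 181 ± 144 RPKM) and SPRR2G (log2 change −2.35), while SPRR1A rose (1143 ± 263 to 2920 ± 471 RPKM, paired adjusted p = 0.0113). The other 28 did not pass, S100A9 (log2 change 0.38, paired adjusted p = 0.260) and SPRR2E (−0.32, paired adjusted p = 0.307) among them. In the unpaired test 0 passed over all genes, and 7 fell and 2 rose adjusted over the list alone; the paired counts adjusted over the list alone were 13 and 3. The list's median log2 change was −0.77, at −0.89 among libraries 1 and 2 and −0.60 among libraries 3 and 4. LCE and SPRR genes are multigene families with similar sequences, so single members are uncertain. The shCtrl means of LCE3D, LCE3E and SPRR2G rest largely on shCtrl 1 (LCE3D 7690 RPKM against at most 1930 RPKM in the other shCtrl libraries, SPRR2G 5140 against at most 1510 RPKM), and without it they were 1160 RPKM for LCE3D and 551 RPKM for LCE3E; without HIF1A-KD 1 the HIF1A-KD means were 229 and 111 RPKM. In the paired fit without shCtrl 1, LCE3D (−2.34), LCE3E (−2.26), SPRR2G (−2.17) and PRR9 (−3.54) still passed, and the other 3 that fell and SPRR1A (adjusted p = 0.0601) did not.

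Suprabasal differentiation genes moved in both directions. In the paired fit 5 of 66 tested members rose and 4 fell. Those that rose were TMPRSS11A, KRT10, CALML3, SERPINB3 and LYPD3, and those that fell were CDSN, which encodes corneodesmosin (49.4 ± 62.5 to 5.71 ± 5.53 RPKM, SD, n = 4 each; paired adjusted p = 0.00488), DMKN (1003 ± 47.9 to 500 ± 13.8 RPKM), the very long chain fatty acid enzyme ELOVL4 (log2 change −1.29) and the kallikrein KLK5 (−1.32). Without shCtrl 1 the shCtrl mean of CDSN was 18.4 RPKM, and without HIF1A-KD 1 its HIF1A-KD mean was 2.97 RPKM. CALML3, SERPINB3 and LYPD3 were named after their values were seen. Over all genes 0 passed unpaired; adjusted over the list alone, 6 rose and 6 fell unpaired, and 17 and 12 in the paired fit. The list as a whole did not pass camera (adjusted p = 0.477), while fry's test for change in either direction gave an adjusted p of 0.00402. The abundant keratins KRT6A (log2 change −0.14, adjusted p = 0.979 unpaired and 0.515 paired) and KRT17 (−0.42, adjusted p = 0.751 unpaired and 0.0819 paired) did not pass. Neither did IVL (0.31), FLG (−0.45) or KRT13, whose log2 change was 2.37 with an adjusted p of 0.464 unpaired and 0.116 paired.

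Genes known to be lowered in eosinophilic esophagitis tissue were higher as a list in HIF1A-KD by camera (adjusted p = 0.000482, and adjusted p = 0.213 with an estimated correlation). CRISP3 was the only 1 of 19 tested members to rise in the paired fit over all genes, and 0 passed unpaired. Adjusted over the list alone, 4 rose and 0 fell unpaired, and 8 rose and 1 fell in the paired fit. Estimates were above 0 for 14 of the 19, with a median log2 change of 0.72, against 58.7% and 0.064 for all tested genes. SPRR3 held 2243 ± 1277 and 5784 ± 992 RPKM (SD, n = 4 each; log2 change 1.57, adjusted p = 0.309), DSG1 had a log2 change of 1.08 (adjusted p = 0.677) and SPINK7 of 0.72 (adjusted p = 0.537), while SPRR2D, an abundant member, held 4691 ± 1134 and 3656 ± 430 RPKM (−0.33, paired adjusted p = 0.239; lower in 4 of 4 pairs). Among libraries 1 and 2 the log2 changes of SPRR3 and SPINK7 were 2.36 and 1.37, and among libraries 3 and 4 they were 0.78 and 0.08. Of 18 genes raised in that disease, 5 could be tested and 0 passed either fit over all genes; adjusted over the list alone, 0 passed unpaired and 2 rose in the paired fit. CAPN14, an esophageal protease gene, had a log2 change of 1.95 (adjusted p = 0.783), CTSC of −0.25 (adjusted p = 0.853), and camera gave an adjusted p of 0.754. CCL26 was too low to test, at 0.27 ± 0.28 and 0.057 ± 0.091 RPKM (SD, n = 4 each). SERPINB4, also a member, was left out by the filter and not tested, at 0.077 ± 0.012 RPKM in shCtrl and 2.16 ± 1.72 RPKM in HIF1A-KD.

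**Figure D3:**
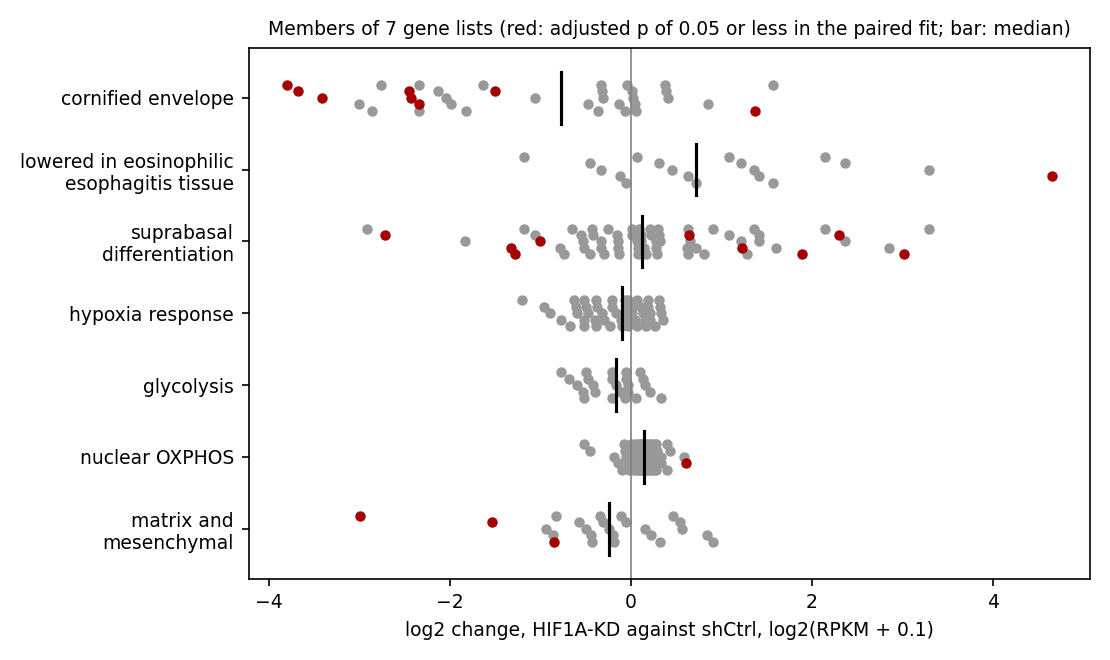
The log2 change of HIF1A-KD against shCtrl for each tested member of 7 gene lists (horizontal axis, log2(RPKM + 0.1) scale), with red points for members at a paired adjusted p of 0.05 or less and a bar at each list's median. The medians were −0.77 for cornified envelope precursors and 0.72 for genes lowered in eosinophilic esophagitis tissue, against −0.10 for hypoxia response genes and 0.14 for nuclear OXPHOS subunits.

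Hypoxia response and glycolysis genes were lower as lists by small amounts (camera adjusted p = 0.00408 and 0.00824), and oxidative phosphorylation genes higher (adjusted p = 0.0183). With an estimated correlation none of the 3 lists passed (adjusted p = 0.619, 0.777 and 0.777). No hypoxia response gene among 49 tested passed either fit, over all genes or adjusted over the list alone; 31 estimates were below 0, with a median of −0.10. Of 25 glycolysis genes 0 passed over all genes, 19 estimates were below 0 with a median of −0.16, and adjusted over the list alone 0 passed unpaired and 2 fell in the paired fit. LDHA, the lactate dehydrogenase subunit, held 438 ± 77.9 and 295 ± 80.6 RPKM (SD, n = 4 each, log2 change −0.59, adjusted p = 0.527 unpaired and 0.174 paired). GAPDH (−0.42, adjusted p = 0.728), PKM (−0.21, adjusted p = 0.883), the glucose transporter SLC2A1 (0.33, adjusted p = 0.815), NDRG1 (0.07), VEGFA (0.19), PDK1 (−0.16) and CA9 (−1.21, adjusted p = 0.882) did not pass. Without shCtrl 2, HIF1A-KD 1 or HIF1A-KD 3 neither list passed (0.0564, 0.056 and 0.229 for hypoxia, 0.373, 0.0707 and 0.258 for glycolysis). Of 74 nuclear OXPHOS subunits 63 had estimates above 0, with a median of 0.14. Among all tested genes 58.7% had estimates above 0, with a median of 0.064, so part of this shift is general. ATP5H rose in the paired fit (80.3 ± 18.8 to 121 ± 16.7 RPKM, paired adjusted p = 0.0460), and 0 passed unpaired or, in both fits, adjusted over the list alone. The OXPHOS list did not pass under median-of-ratios scaling (adjusted p = 0.0629) or without shCtrl 1 (0.219), shCtrl 4 (0.157), HIF1A-KD 1 (0.0707) or HIF1A-KD 2 (0.365), and ATP5B (0.16, adjusted p = 0.985) and ATP5A1 (−0.07, adjusted p = 0.996) did not pass. TCA cycle genes did not pass as a list (adjusted p = 0.776) or singly, in either fit or adjusted over the list alone, and CS, the citrate synthase gene, held 59.7 ± 2.10 and 59.7 ± 3.00 RPKM (SD, n = 4 each), with OGDH at a log2 change of 0.007.

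The matrix and mesenchymal list and the cytokine list were lower in HIF1A-KD by camera (adjusted p = 0.00125 and 0.0179), with 3 of 25 and 2 of 19 tested members falling in the paired fit. Neither passed with an estimated correlation (adjusted p = 0.213 for each), and 8 estimates in each were above 0. Besides FN1, the intermediate filament gene VIM fell in the paired fit from 55.1 ± 7.18 to 20.02 ± 7.78 RPKM (SD, n = 4 each; paired adjusted p = 0.0163), and TGFBI from 429 ± 116 to 232 ± 20.1 RPKM (paired adjusted p = 0.0407). The tropomyosin gene TPM1, which is in none of the lists, fell from 67.5 ± 18.1 to 24.1 ± 8.60 RPKM (paired adjusted p = 0.00435). Of the matrix and mesenchymal genes 1 fell in the unpaired test; adjusted over the list alone, 3 fell and 1 rose unpaired, and 5 and 1 paired. That list did not pass without HIF1A-KD 1 (0.073). Among 4 tested fibroblast markers MFAP5 fell in the paired fit (17.6 ± 3.26 to 8.21 ± 3.29 RPKM). COL1A1 did not pass (−0.61, adjusted p = 0.319 unpaired and 0.0920 paired). Adjusted over the list alone 2 fell in each fit, and camera gave adjusted p = 0.000335, or adjusted p = 0.190 with an estimated correlation. The inflammatory cytokine IL1B (389 ± 86.6 to 129 ± 31.9 RPKM) and the growth factor CSF3 (3.08 ± 0.75 to 0.76 ± 0.28 RPKM) fell in the paired fit (adjusted p = 0.0365 and 0.0403), and 0 cytokines passed unpaired; adjusted over the list alone, 2 fell unpaired, and 3 fell and 1 rose paired. TGFA had a log2 change of −0.49 (adjusted p = 0.409 unpaired and 0.0781 paired) and IL1RN of 0.13. The cytokine list did not pass camera in the paired fit (adjusted p = 0.0644) or without shCtrl 4 (0.0678), HIF1A-KD 1 (0.073) or HIF1A-KD 2 (0.125).

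Interferon-stimulated genes were higher as a list by camera (adjusted p = 0.0145, and adjusted p = 0.619 with an estimated correlation). GBP2 rose in the paired fit (0.856 ± 0.325 to 4.18 ± 2.2 RPKM, SD, n = 4 each; paired adjusted p = 0.0163) as the only 1 of 28 tested. Adjusted over the list alone, 2 rose unpaired and 6 in the paired fit, and SAMD9 (0.65) did not pass. The list did not pass without shCtrl 1 (0.219) or HIF1A-KD 4 (0.118). Lipid synthesis genes were lower as a list (camera adjusted p = 0.00125, and adjusted p = 0.226 with an estimated correlation). Of 26 members ELOVL4 fell in the paired fit, and adjusted over the list alone 1 fell unpaired and 3 paired. SCD (−0.44, adjusted p = 0.536 unpaired and 0.157 paired) and FABP5 (0.03) did not pass. The cholesterol synthesis list did not pass (adjusted p = 0.971; median −0.03, mean 0.06), although its reductase gene TM7SF2 rose in the paired fit (26.1 ± 4.51 to 54.0 ± 19.4 RPKM, paired adjusted p = 0.0299); 2 members rose paired and 0 unpaired adjusted over the list alone.

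Basal layer genes were slightly lower as a list by camera (adjusted p = 0.0183, and adjusted p = 0.213 with an estimated correlation), and junction genes were not called as lists. CDH3, which encodes P-cadherin, fell in the paired fit from 120 ± 33.5 to 68.5 ± 19.7 RPKM (SD, n = 4 each; paired adjusted p = 0.0163), and CDH1, which encodes E-cadherin, from 159 ± 36.8 to 95.2 ± 35.8 RPKM (paired adjusted p = 0.0318). CDH3 was the only 1 of 24 basal genes to pass over all genes; adjusted over the list alone 4 fell and 2 rose paired and 0 passed unpaired, and KRT5 (−0.06) and KRT14 (0.13) did not pass. The basal list did not pass without shCtrl 3 (0.0779), shCtrl 4 (0.0678), HIF1A-KD 1 (0.073) or HIF1A-KD 2 (0.137). Of 21 adherens junction and desmosome genes 2 fell in the paired fit; adjusted over the list alone 2 fell and 1 rose paired and 0 passed unpaired, DSP (−0.08) and JUP (0.01) did not pass, and the list did not pass (adjusted p = 0.929, lower, with a median of 0.007). No tight junction gene of 22 passed either fit, over all genes or adjusted over the list alone (camera adjusted p = 0.767), with CLDN1 at 117 ± 45.7 and 114 ± 45.8 RPKM (SD, n = 4 each) and CLDN4 at a log2 change of 0.60 (adjusted p = 0.761).

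Among the remaining lists, camera called none in the main setting with all libraries, while proliferation passed at a filter of 1 RPKM. Proliferation passed without shCtrl 3 (0.0499), shCtrl 4 (0.0258) or HIF1A-KD 2 (0.0348), the unfolded protein response without shCtrl 2 (0.017) or HIF1A-KD 3 (0.0459), and p53 targets without HIF1A-KD 3 (0.034). FTL, the ferritin light chain, fell in the paired fit (1255 ± 251 to 792 ± 125 RPKM, SD, n = 4 each; paired adjusted p = 0.0459) as 1 of 22 NRF2 targets, where FTH1 had a log2 change of 0.22 (list adjusted p = 0.288; adjusted over the list alone, 4 fell and 2 rose paired and 0 unpaired). TP53I3 rose in the paired fit (10.2 ± 1.89 to 20.7 ± 6.01 RPKM, paired adjusted p = 0.0373) as 1 of 26 p53 targets, with CDKN1A at −0.01 and GADD45A at −0.11 (list adjusted p = 0.322; 1 rose paired and 0 unpaired adjusted over the list alone). No member passed over all genes among 16 proliferation genes (PCNA −0.26, MCM4 −0.09; list adjusted p = 0.153), 22 Notch genes (JAG1 −0.59, NOTCH1 −0.49; 0.594), 25 genes of the unfolded protein response (HSPA5 −0.15, CALR −0.26; 0.288) or 7 columnar epithelium markers (KRT19 1.35, KRT18 0.21; 0.640). Adjusted over the list alone, 2 Notch genes and 1 columnar marker rose in the paired fit, and 0 of the others passed. MKI67 was at 0.014 ± 0.014 and 0.027 ± 0.015 RPKM. Leukocyte, endothelial and melanocyte lists had fewer than 3 tested members; PTPRC, TYROBP and SOX10 were listed at 0 in all libraries, while CD68 held 71.2 ± 40.2 and 51.0 ± 27.6 RPKM, VWF 4.71 ± 7.08 and 5.10 ± 5.24 RPKM and PMEL 0.67 ± 0.24 and 0.98 ± 0.75 RPKM (SD, n = 4 each).

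The labels do not say whether libraries came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Each arm was a single transduced line, so the hairpin, its off-target effects and the line cannot be separated from HIF1A itself.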

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

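Among the named genes, 206 sets of 4 libraries were examined for a library far from the other 3, and 13 stood out where chance gives about 10.3. The tests of length and of abundant genes were planned before their results were seen; the others below, those of libraries 1 and 2 against 3 and 4 included, were chosen afterwards. The test on suprabasal members replaced an earlier one on their median log2 change, 0.13, which decides nothing where members go both ways.

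In HIF1A-KD, library 1 stood apart for VEGFA (178 RPKM against 49.6 to 53.3 RPKM, gap 0.943 of the range), AZGP1 (36.1 against 19.1 to 19.9 RPKM, 0.937), JUP (950 against 1190 to 1210 RPKM, 0.918) and FTH1 (5790 against 4210 to 4360 RPKM, 0.888). Library 2 stood apart for CLDN1 (46.9 against 124 to 146 RPKM, 0.854), and library 3 for SLC2A1 (218 against 319 to 338 RPKM, 0.864), FN1 (20.9 against 7.90 to 8.81 RPKM, 0.888) and COL1A1 (19.2 against 14.1 to 14.8 RPKM, 0.845). In shCtrl, library 1 stood apart for FLG (93.2 against 7.50 to 11.1 RPKM, 0.845), SPRR2G (5140 against 1170 to 1510 RPKM, 0.831) and PSG7 (11.9 against 0.62 to 1.04 RPKM, 0.833). There, library 2 stood apart for ATP5H (108 against 68 to 72.5 RPKM, 0.865) and library 4 for CS (62.9 against 58.6 to 58.7 RPKM, 0.962).

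The cornified envelope list was lower in HIF1A-KD by camera (adjusted p = 2.49e-06, and adjusted p = 0.213 with an estimated correlation), with 7 of 36 members falling and SPRR1A rising in the paired fit and 0 passing unpaired. Poor recovery of short transcripts would also lower other short genes, yet 10000 random lists matched on length had medians around 0.07 and at lowest −0.21, against −0.77, which put the list at percentile 0. The split of libraries 1 and 2 from 3 and 4 is balanced over the groups, and the list's median was −0.597 in libraries 3 and 4, where it was nearer 0. A lower yield of all suprabasal genes would raise none, yet 5 of 66 suprabasal members rose in the paired fit, where the share of all genes that rose gives 0.488, while 4 fell, so a lower yield of some of them stays open. Also open is an effect of HIF1A, of the hairpin or of a transduced line, and culture maturity that differs between the groups. In the paired fit without shCtrl 1, LCE3D (−2.34), LCE3E (−2.26), SPRR2G (−2.17) and PRR9 (−3.54) still passed, so shCtrl 1 alone does not account for their falls. LCE2A (−3.13), LCE2C (−2.89), CRCT1 (−1.52) and SPRR1A (1.43) did not pass. For the list, camera at the preset correlation gave adjusted p = 1.77e-05 without shCtrl 1. An estimated correlation was not run there, so the list's dependence on shCtrl 1 stays open.

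FN1, VIM and TGFBI, 3 of 25 matrix and mesenchymal genes, fell in the paired fit. The 4 tested fibroblast markers also had estimates below 0 (camera adjusted p = 0.000335, and adjusted p = 0.190 with an estimated correlation), among them MFAP5 and COL1A1 at 17.6 and 23.7 RPKM in shCtrl. Fewer fibroblast-like cells are argued against by the other abundant transcripts such cells would bring: the median over all 14 markers was 0.0263 RPKM in shCtrl, with COL1A2 at 0.00107 RPKM and COL3A1 and DCN listed at 0 in its 4 libraries. The split of libraries 1 and 2 from 3 and 4 is balanced over the groups, so by itself it cannot give a difference between group means, and FN1 is no test of it. FN1 was at −2.73 in libraries 3 and 4, where its change was nearer 0. An effect of HIF1A or of the transduced line stays open and untested.

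HIF1A-KD libraries 3 and 4 resembled the shCtrl library of the other number. The difference of library 3 from 4 correlated across genes at −0.292 between the groups, while that of 1 from 2 correlated at 0.748. A shared batch alone would give a value near 0, and counting noise would fade among abundant genes, where the correlation was −0.684 over 1259 genes of at least 50 RPKM. Exchanged numbers within a group may account for it (−0.292); cultures that happened to reach a like state would give the same value and stay open. Genes are not independent replicates, and an exchange within a group leaves the unpaired test as it is.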

How the results depend on the processing

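Pseudocounts, the split of libraries 1 and 2 from 3 and 4, crossed numbers, the authors' table, the settings of the paired fit and the block with estimated correlation were chosen after seeing the data. The count of 5 changed genes (3 higher, 2 lower, 5 at least 2-fold) became 8 (5 lower, 8 at least 2-fold) with median-of-ratios scaling, 1 without a filter (1 higher, 0 lower, 1 at least 2-fold) and 3 at pseudocounts of 1 and 0.01 (1 higher, 3 at least 2-fold). Limma-voom gave 1 higher and 4 lower. The replicate block gave 218 (88 higher, 130 lower, 132 at least 2-fold), with HIF1A at −1.34 now past the threshold and cytokines at 0.0644, no longer past it; it changed no other list's call, and tight junction genes, at 0.984 and not past the threshold in either fit, only turned direction. With the split as a term there were 102 (41, 61 and 70), in libraries 1 and 2 alone 0 (0, 0 and 0), and in libraries 3 and 4 alone 1 higher and 4 lower. A block with HIF1A-KD 3 and 4 crossed gave 1327 (751, 576 and 296; HIF1A −1.34). The authors' deposited table holds 1229 (537, 692 and 254). The 254 rest on moderated fold ratios and are not a like count to the others of at least 2-fold. The paired count of 218 became 23 without a filter (7, 16 and 22), 335 with voom (209 lower), 33 with pair 1 left out (10, 23 and 31) and 1 with pair 2 left out (1, 0 and 1). Leaving out single libraries gave 0 to 3 changed genes unpaired (0 to 1 higher, 0 to 2 lower, 0 to 3 at least 2-fold) and 1 to 239 paired (1 to 103, 0 to 136 and 1 to 166), with the lowest counts without shCtrl 1 (20), shCtrl 2 (5), HIF1A-KD 1 (33) and HIF1A-KD 2 (1). HIF1A ran from −1.59 to −1.07. With an estimated correlation no list passed: hypoxia 0.619, glycolysis 0.777, OXPHOS 0.777, cornified envelope 0.213, basal 0.213, interferon 0.619, cytokines 0.213, genes lowered in eosinophilic esophagitis 0.213, lipid 0.226, matrix 0.213 and fibroblast 0.190. With the block as well these were 0.786, 0.786, 0.804, 0.435, 0.439, 0.786, 0.439, 0.439, 0.435, 0.527 and 0.435, and tight junction 0.984. Fry in a single direction gave, in the same order, 0.646, 0.720, 0.361, 0.344, 0.361, 0.344, 0.239, 0.0972, 0.344, 0.284 and 0.0723, with adherens junctions at 0.833 and cholesterol at 0.920. Fry in either direction gave hypoxia, glycolysis and OXPHOS 0.641, cornified envelope 0.102, basal 0.479, interferon 0.175, lowered in esophagitis 0.0841, lipid 0.351 and fibroblast 0.0841, while matrix (3.43e-05) and cytokines (0.00043) passed, as did the suprabasal list (0.00402), which had not passed camera. OXPHOS lost its call under median-of-ratios scaling (0.0629), and proliferation passed at a filter of 1 RPKM (0.0234). Leaving out single libraries, the adjusted p ran over 1.85e-05 to 0.229 for hypoxia, 0.000182 to 0.373 for glycolysis, 0.00049 to 0.365 for OXPHOS, 0.00483 to 0.137 for basal, 0.00246 to 0.219 for interferon, 0.00644 to 0.125 for cytokines, 5.2e-05 to 0.073 for matrix, 0.0258 to 0.718 for proliferation, 0.017 to 0.974 for the unfolded protein response and 0.034 to 0.997 for p53, where calls came or went. It was 0.263 to 0.997 for the TCA cycle, 0.444 to 0.913 for tight junctions, 0.473 to 0.982 for adherens junctions and 0.111 to 0.638 for cholesterol. Calls held for cornified envelope (4.16e-07 to 3.14e-05), genes lowered in esophagitis (1.79e-05 to 0.00562), lipid (0.0003 to 0.01) and fibroblast (1.13e-05 to 0.00156). No called value reversed. For named genes called in the paired fit this was fixed beforehand where a library was left out, since all 4 pairs moved the same way. For named genes, values unpaired were on the same side in 1674 cases, newly past the threshold in 117, no longer past it in 51 and moved in 89, and paired in 1441, 13, 298 and 95. The cause of these changes was not tested. Leaving out mitochondrially encoded genes was not run because the table used holds none, and the planned count tests were not run on the recovered reads, on which limma-voom was. The implied depth was 38068729 to 65326907 reads, and what depth limits was not tested.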

Other observations

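The tests of the gene scores below were chosen after the values were seen; the counts over splits of the libraries were planned before.

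Among genes that the rule for named genes had not taken, several typical of esophageal mucosa had large estimates without passing the unpaired or paired test. KRT4, the mucosal partner of KRT13, held 386 ± 242 and 1521 ± 355 RPKM (SD, n = 4 each; log2 change 2.15, adjusted p = 0.107 unpaired and 0.0786 paired), and CLCA4 30.8 ± 31.4 and 149 ± 68.8 RPKM (2.99, adjusted p = 0.380). TMPRSS11B held 3.67 ± 0.46 and 36.7 ± 35.4 RPKM (2.86, adjusted p = 0.115). Some epidermal genes went the other way: LOR, which encodes loricrin, held 19.2 ± 17.8 and 3.93 ± 4.47 RPKM (−2.92, adjusted p = 0.659) and CASP14 5.75 ± 6.47 and 0.85 ± 0.31 RPKM (−2.11, adjusted p = 0.392). All 5 moved the same way in 4 of 4 pairs, and they were picked after their values were seen. Against this grouping, the epidermal keratin KRT10 rose in the paired fit (2.30, paired adjusted p = 0.0432, higher in 4 of 4 pairs), KRT1 was at 0.91 and KRT2 at 0.88, and the mucosal genes RHCG, EMP1 and KRT78 were at −0.30, −0.20 and −0.14.

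A hypothesis is that HIF1A-KD cultures may have shifted from an epidermal towards a mucosal end state. For 15 mucosal and 18 epidermal genes that the rule for named genes had not taken, which leaves out KRT10, the mean log2 RPKM of the first minus that of the second was 0.79 ± 2.55 in shCtrl and 3.73 ± 1.10 in HIF1A-KD (SD, n = 4 each). The difference was higher in 4 of 4 pairs, the mucosal mean alone in 3 of 4 (two-sided exact permutation p = 0.0571), and the epidermal mean alone was lower in 4 of 4 (two-sided exact permutation p = 0.114). For the difference a two-sided exact permutation test without the pairing gave p = 0.0571, where the smallest possible is 0.0286. Since the score holds the 5 genes picked above, the test decides nothing and the hypothesis stays open.

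A second hypothesis is that contractile and actin genes may be lower. Over 20 tested members that the rule for named genes had not taken the mean log2 RPKM was 5.94 ± 0.165 in shCtrl and 5.47 ± 0.165 in HIF1A-KD (SD, n = 4 each), lower in 4 of 4 pairs. The two-sided exact permutation p, without the pairing, was 0.0286, the smallest that 4 against 4 can give. The list was written after values were seen and holds MYL9, so this p decides nothing, and the hypothesis stays open. MYL9, a myosin light chain gene, held 29.8 ± 6.52 and 6.48 ± 3.00 RPKM (log2 change −2.29, adjusted p = 0.0629 unpaired and 0.0253 paired).

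Chance was not excluded for the unpaired count: 3 of the 35 splits of the 8 libraries into 4 and 4 called at least as many genes as the real 5. The highest other, 2748, was the split of libraries 1 and 2 from 3 and 4, which points to a structure of the samples, and the counts within libraries 1 and 2 and within 3 and 4 were 0 and 5. Another split, with shCtrl 1 and 4 and HIF1A-KD 1 and 3 on the same side, called 62. It keeps together shCtrl 4 and HIF1A-KD 3 (correlation 0.613), and shCtrl 3 and HIF1A-KD 4 (0.463). These libraries deviated together, so that split too follows a structure of the samples. The remaining 32 called 0. For the paired fit, 8 splits part all 4 pairs, too few for a share under 0.05; the real split called 218 and the highest other 0, and it was the only 1 to reach 218. For the gene lists, 3 of 35 splits gave at least as many lists past the threshold as the real 11, with 11 the highest other and a median of 5, so chance was not excluded there either. Both other splits at 11 part 2 pairs; among the 8 that part all 4 pairs, too few for a share under 0.05, the highest other gave 10 lists and, in the unpaired test, 0 genes.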
